A study of Synthetic plasmid and Mus musculus with 4 samples.

How the data were processed

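The series holds a reporter library made by capturing sonicated C57BL/6J genomic DNA around target sites with biotinylated RNA baits and cloning the fragments into barcoded plasmids, per the labels. Paired-end sequencing of 250 bp reads linked each barcode to its fragment, and single-end 50 bp reads counted barcodes in RNA and DNA, per the labels. The 6 libraries of a tissue shared one lane. The submitters' processing notes name FastQC, Bowtie2 2.1.0, SAMtools 0.1.19, bedtools 2.22.1 and the mouse build mm9, with no roles. The labels say that replicates came from separate sets of 5 retinas or from separate animals.

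The authors deposited raw barcode counts per construct for the 3 RNA and 3 DNA libraries of each tissue, per the file headers. They also deposited, for constructs with at least 10 counts in every DNA library of the tissue, each library's counts as a fraction of its total, the RNA to DNA ratio of these fractions, and log2 of the ratio plus 0.001, per the file headers and the values. These log2 values were recomputed from the counts within 5e-10. The construct table was deposited once for each of 2 plasmid preparations, and both copies were identical, so it was used once. It lists for each barcode the fragment's position, the target it overlaps and a read count of at least 10. Fragments had a median length of 464 bp (180 to 702), and a target had a median of 8 constructs (at most 129). Start positions count from 0 in the deposited table and are given here counted from 1. Barcode reads carry no molecular identifiers that were used here, so intervals and floors cover counting error only.

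Activity was tested on the counts with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, trimmed mean of M values scaling, Benjamini-Hochberg, threshold 0.05), as RNA against DNA. The biological replicate was a block, since RNA and DNA of a replicate came from the same tissue sample per the labels. The deviations of paired RNA and DNA libraries correlated between -0.044 and 0.018, so the block rests on the labels and not on these values. Constructs needed at least 10 DNA counts in each DNA library. A region is a target, its counts are sums over its constructs, and at least 5 constructs were needed. The retina minus cortex difference was an interaction over all 12 libraries on constructs passing in both tissues. SEs were obtained from the fold change and the F statistic. Retina RNA factors were 0.277 to 0.317 and DNA factors 3.41 to 3.43 in the region fit, where R constructs took most RNA. A log2 of 0 is the level set by this scaling, and neither equal RNA and DNA shares nor the median region, which lay at -1.96 in retina, -0.09 in cortex and -1.80 for retina minus cortex.

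Classes were compared by two-sided permutation tests over regions (100000 resamples, smallest p 1e-05) and Fisher's exact tests, each adjusted over the 4 classes. Overlap tests needed at least 2 constructs on each side in a region. Per-replicate and per-construct log2 RNA/DNA used a prior count of 2. The regions named were fixed before the data were examined as, per tissue, the 10 highest and 5 lowest log2 RNA/DNA past an adjusted p of 0.05 with the same sign in all 3 replicates, and the 10 largest retina minus cortex differences in each direction. In the top 2 regions of a tissue, the most and least active constructs were named. Only 3 regions qualified as lowest in retina and none in cortex. Regions called outside the class of their tissue are named in the closing part because they are few, and were chosen after their values were seen.

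The fits were tested on simulated counts with 200 changed features, 50 per fold. Among regions in retina, 0% of 4-fold, 40% of 16-fold and 100% of 64-fold increases were called; in cortex 98% of 4-fold increases were called. For retina minus cortex these shares were 0% at 4-fold, 38% at 16-fold and 86% at 64-fold. Fitted sizes were too large in retina, where 4-fold increases lay at a median log2 of 3.52 over unchanged regions and 64-fold ones at 8.19. For retina minus cortex these medians were 3.41 and 7.8, while in cortex they were 2.03 and 6. Among constructs, no increase up to 1024-fold was called in retina, and in cortex 24% at 64-fold and 94% at 1024-fold. All unchanged features of a tissue shared 1 RNA/DNA ratio in the simulation, unlike the real classes. The real fit called 838 constructs higher in retina, so the simulation does not reproduce these data. Alternatives were another scaling, DESeq2 1.42.0, limma 3.58.1 on mean construct ratios, no block, other count and construct minimums, and each replicate left out. The mean construct ratios were centred on the median region of each replicate, so their zero differs from that of the edgeR fits. Constructs without RNA enter these means at a value set by the prior count and their DNA counts. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest. The deposited mean log2 values of the authors correlated with those computed here with a Spearman rho of 0.561 in retina and 0.921 in cortex, and a Pearson r of 0.875 and 0.913, across constructs. Genes near the regions, motifs and GC content were not analysed here.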

Results

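Cis-regulatory activity was measured with a barcoded reporter library in mouse retina and mouse cerebral cortex. Each construct carried one captured genomic fragment and one transcribed barcode, so the barcode counts in RNA, relative to those in DNA, report how strongly the fragment drove transcription. The library held 45670 constructs with fragments from 3483 target regions. A target belonged to one of 4 classes, marked by the letters R, B, H and L. From knowledge of the study these letters are read as DNase hypersensitive sites of retina, brain, heart and liver; the tables used here give only the letters. The R class held 858 targets with 11319 constructs, the B class 828 with 10505, the H class 859 with 10842 and the L class 938 with 13004. Retinas of CD-1 mice were electroporated at birth and cultured for 8 days, with 3 biological replicates of 5 retinas each. Cortex of CD-1 mice received the library in an adeno-associated virus at 4 to 6 weeks of age and was collected 4 to 5 weeks later from GFP-positive regions, with 3 replicates of 1 animal each. RNA and DNA were counted in every replicate. Retina libraries held 7025820 to 10411511 RNA counts and 6501061 to 12147398 DNA counts, and cortex libraries 4000439 to 9674859 RNA counts and 3999412 to 10769648 DNA counts. At least 10 DNA counts in each DNA library were found for 36005 constructs in retina and 38826 in cortex.

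The first question was whether fragments of a class drove transcription in the tissue from which the class was taken. In retina, R constructs gave 94.2% ± 0.50 of the RNA counts but 25.0% ± 0.19 of the DNA counts (SD, n = 3). Their RNA share was thus 3.77 ± 0.035 times their DNA share. The same ratio was 0.089 ± 0.005 for B, 0.077 ± 0.004 for H and 0.069 ± 0.010 for L constructs. In cortex, B constructs gave 38.2% ± 1.81 of the RNA counts and 23.0% ± 0.11 of the DNA counts, a ratio of 1.66 ± 0.078 (SD, n = 3). The ratio in cortex was 0.818 ± 0.026 for R, 0.818 ± 0.023 for H and 0.776 ± 0.027 for L constructs. These shares do not depend on a scaling between libraries.

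**Figure D1:**
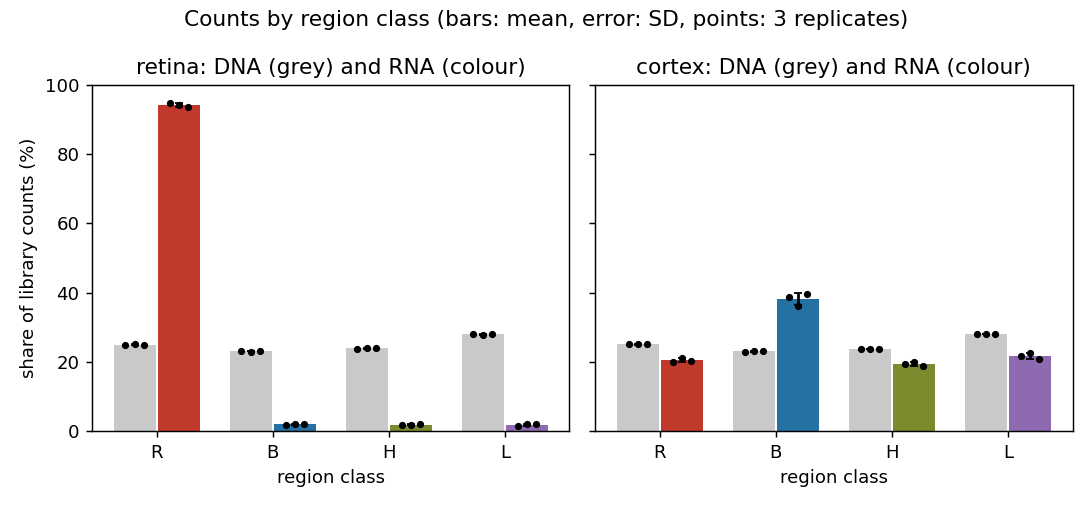
Share of library counts (%) taken by the constructs of each region class in retina and cortex, for DNA (grey) and RNA (colour); bars are means, error bars SD and points the 3 replicates. R constructs took 94.2% of retina RNA and B constructs 38.2% of cortex RNA, with DNA shares of 25.0% and 23.0%.

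RNA was detected for fewer constructs in retina than in cortex. In retina, 64.3% of the constructs had no RNA count in any replicate and 5.99% had RNA in all 3. In cortex these shares were 12.5% and 32.7%. Per replicate, RNA was seen for 37.5% ± 3.59 of R constructs in retina, against 12.1% ± 2.04 of B, 11.4% ± 2.06 of H and 11.2% ± 2.75 of L constructs (SD, n = 3). In cortex it was seen for 64.8% ± 5.67 of B, 60.5% ± 6.09 of H, 60.0% ± 6.05 of R and 59.3% ± 5.79 of L constructs. B had the highest share in 3 of 3 cortex replicates, although the replicates differed from one another by more than the classes did.

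At the level of regions, the R class carried nearly all activity called in retina. Counts were summed over the constructs of a region, and 2031 regions with at least 5 constructs were tested. RNA exceeded DNA, relative to the level set by the scaling, in 177 of 477 R regions, which is 37.1% (95% exact binomial interval 32.8 to 41.6). That level lay above the median region, at a log2 of -1.96 (0.932 for R regions and -2.516 for all others). RNA exceeded it in 2 of 439 B regions, in 0 of 489 H regions and in 0 of 626 L regions (edgeR quasi-likelihood test, adjusted p under 0.05). The R share exceeded that of the other classes, 0.13% (Fisher's exact test, two-sided, adjusted p = 2.32e-120). The 177 R regions held 92.3% ± 0.69 of the RNA counts and 10.6% ± 0.09 of the DNA counts (SD, n = 3), and their log2 RNA/DNA ranged from 1.57 to 9.71 with a median of 5.30. The median log2 RNA/DNA of R regions exceeded that of all other regions by 3.45 (two-sided permutation test over regions, p = 1e-05, the smallest it can give, adjusted p = 2e-05). With construct means in limma this difference was 0.937 (permutation test, adjusted p = 2e-05). Those means weigh constructs without RNA equally with the rest, so the limma and edgeR sizes are not directly comparable. Simulated 4-fold increases were fitted at a median log2 of 3.52 in retina, so edgeR sizes there may be overstated. Against H and L regions alone the R median was higher by 3.94 ± 0.55 (SD, n = 3), in 3 of 3 replicates. Scaling by total library size instead gave 89 regions higher and 924 lower, against 179 and 3 with the trimmed-mean scaling. The number of lower regions also moved with the replicate block (113 without it) and the method (438 in DESeq2), and RLE size factors gave 3.

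The 10 regions with the highest activity in retina were R regions. The highest was R154, with a 300 bp window on chromosome 19 from 42645866 to 42646165 (mm9), where log2 RNA/DNA was 9.71 (SE 0.21) from 337753 RNA and 5366 DNA counts over 6 constructs. R321 followed at 9.43 (SE 0.20) on chromosome 6 from 3925746 to 3926045. R368 reached 9.39 (SE 0.20) on chromosome 14 from 52727746 to 52728045. R392, on chromosome 11 from 67495426 to 67495725, reached 9.35 (SE 0.13) and alone gave 2502288 RNA counts from 28 constructs. R366 on chromosome 9 from 106216566 to 106216865 had 9.29. R539 on chromosome 1 from 77657066 to 77657365 had 9.13, and R24 on chromosome 6 from 60691746 to 60692045 had 9.05. R332 on chromosome 13 from 92998046 to 92998345 had 9.04, R349 on chromosome 5 from 108818806 to 108819105 had 8.99, and R64 on chromosome 19 from 53864126 to 53864425 had 8.88. The largest edgeR adjusted p among the 10 was 1.09e-289 (R539); such values rest on a spread shared over all regions, with 3 replicates. The level depends on the scaling: with total library size the values of all regions moved by a log2 of -3.54 in the median, and the 10 regions lay between 5.33 and 6.16 (R154 at 6.16, R321 at 5.88, R64 at 5.33). The same 10 regions had a log2 RNA/DNA between -1.05 and 0.27 in cortex, and none of them passed the test there (adjusted p from 0.432 to 0.988).

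Only 3 regions were called lower in retina, R696 (log2 -4.94, SE 1.61, chromosome 7 from 4083626 to 4083925), B173 (-4.19, SE 1.39, chromosome 8 from 86950526 to 86950825) and B962 (-3.32, SE 1.09, chromosome 2 from 154391346 to 154391645). Their edgeR adjusted p-values were 0.0247, 0.0297 and 0.0273. Lower means below the level set by the scaling, and not below a typical inactive region. The median log2 was -2.514 for H and -2.825 for L regions, and B962 lay within its SE of both. Neither of the fits without retina replicate 1 or 2 called any region lower, and 2 were called without replicate 3. Without the replicate block the log2 values of the 3 regions were -2.81, -1.74 and -2.01 (edgeR adjusted p of 0.414, 0.662 and 0.394). Construct means in limma gave -0.50, -0.38 and -0.40 (limma adjusted p of 0.273, 0.467 and 0.382). These means are centred on the median region, and most retina constructs had no RNA. Large negative values were therefore hardly possible in limma, and its lost calls say little. The test called 0.15% of regions lower, and 0.819% of unchanged simulated regions. That rate would cover all 3 regions. The simulated regions shared 1 RNA/DNA ratio, unlike the real classes, so it does not settle whether the 3 are false calls.

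In cortex, B regions were the most active class, with smaller differences than those of R regions in retina. RNA exceeded DNA in 55 of 461 B regions, which is 11.9% (95% exact binomial interval 9.12 to 15.2), in 7 of 494 R regions, 1 of 508 H regions and 0 of 645 L regions (edgeR, adjusted p under 0.05). The B share exceeded the 0.49% of the other classes (Fisher's exact test, two-sided, adjusted p = 9.56e-29). The 55 B regions held 20.9% ± 1.68 of the RNA counts and 3.09% ± 0.02 of the DNA counts (SD, n = 3), with a median log2 RNA/DNA of 2.23 and a range from 0.90 to 5.98. The median of B regions exceeded that of all other regions by 0.161 (two-sided permutation test, adjusted p = 4e-05), and exceeded H and L regions by 0.178 ± 0.053 (SD, n = 3) in 3 of 3 replicates. R regions did not pass in cortex (difference of medians -0.016, adjusted p = 0.606). No region was called lower by edgeR, where DESeq2 called 26; 229 regions had an unadjusted edgeR p under 0.05 in either direction.

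The highest region in cortex was B662, on chromosome 15 from 91444486 to 91444785, with a log2 RNA/DNA of 5.98 (SE 0.22, edgeR adjusted p = 1.36e-10). B880 on chromosome 17 from 73621306 to 73621605 reached 5.43 (SE 0.17, adjusted p = 1.84e-11) from 22 constructs. B793 on chromosome 9 from 107863646 to 107863945 had 4.77. B645 on chromosome 5 from 112750026 to 112750325 had 4.50. B922 on chromosome 8 from 4256966 to 4257265 had 4.43. R885 on chromosome 10 from 11037886 to 11038185 had 4.14. B352 on chromosome 6 from 144966866 to 144967165 had 4.11, but fell to -0.01 when the construct with most RNA counts was left out of each region. B701 on chromosome 15 from 80108866 to 80109165 had 4.09 from 78 constructs. B885 on chromosome 9 from 108039906 to 108040205 had 4.06, and R523 on chromosome 2 from 29682406 to 29682705 had 4.06. Of these 10, B352 (3.52, adjusted p = 2.17e-08) and R523 (3.82, adjusted p = 3.01e-06) were also called higher in retina. Without its top construct B352 was at -1.3 in retina (SE 3.22, edgeR adjusted p = 0.786), so its call there was lost too.

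**Figure D2:**
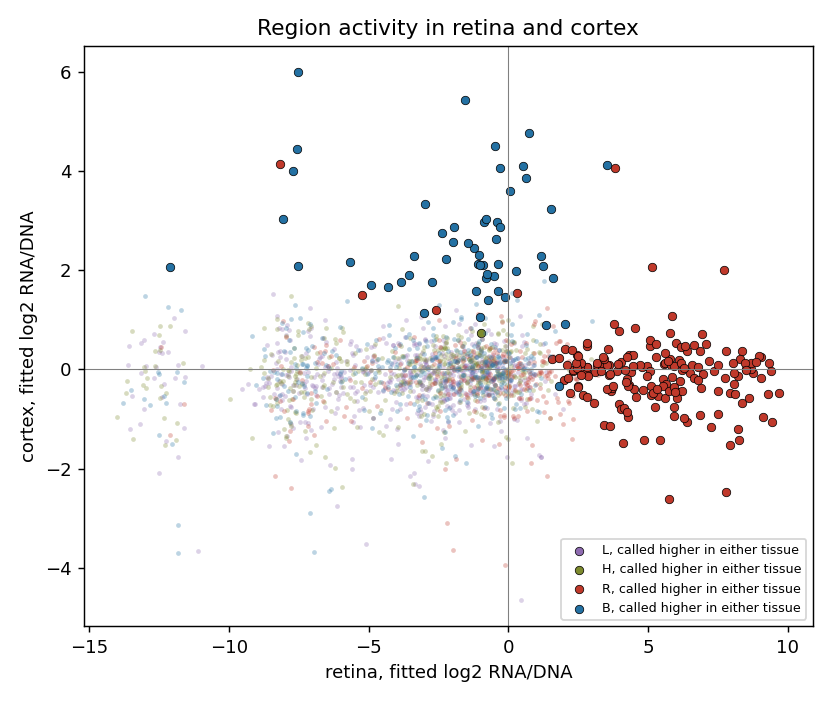
Fitted log2 RNA/DNA of each region in retina (x axis) and cortex (y axis), coloured by class; outlined points were called higher in at least one tissue. Outlined R regions lie to the right, up to 9.71, and outlined B regions lie toward the top, up to 5.98; points far to the left have few or no RNA counts in retina, and their fitted position there is no measured level.

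The next question was whether activity differed between the tissues, tested as an interaction over the 12 libraries in 2000 regions. Tissue was tied to delivery, age and sequencing lane, so the difference belongs to all of these together. Higher activity in retina was called for 167 regions, 166 of them R regions (35.2% of 471 R regions, Fisher's exact test, adjusted p = 1.31e-113). Of the 176 R regions called in retina that could be tested, 164 were also higher in retina than in cortex (87 with total library size, 142 to 175 in the other fits that tested 176). Of the 54 B regions called in cortex that could be tested, 17 were higher in cortex than in retina. This count is fragile: it was 7 to 8 with any cortex replicate left out, 36 in DESeq2, 43 with construct means in limma and 50 with total library size. The difference of R regions exceeded that of the other regions by 3.66 in the median (two-sided permutation test, adjusted p = 2e-05), and by 1.292 with construct means in limma (adjusted p = 2e-05). It was lower for B by -0.861, for H by -0.867 and for L by -0.972, with adjusted p of 6e-05, 5.33e-05 and 2e-05. The other regions include the R regions there, so these differences largely restate the R excess: the medians were 1.227 for R, -2.457 for B, -2.442 for H and -2.414 for L. Construct means in limma gave -0.401 for B, -0.235 for H and -0.089 for L (adjusted p of 2e-05, 5.33e-05 and 0.12), so the L difference did not pass there. Regions called higher in both tissues numbered 4, against 5.5 for independent lists (Fisher's exact test, two-sided, p = 0.652). The lists were mostly R regions in retina and B regions in cortex. This comparison over all classes therefore cannot say whether sharing within a class exceeded chance.

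R321 showed the largest difference in favour of retina, a log2 of 10.57 (SE 0.30, edgeR adjusted p = 3.76e-09). R167 followed with 10.27 (SE 1.27, chromosome 12 from 51715406 to 51715705), then R154 with 10.26 and R539 with 10.13. R366 had 9.86, R335 had 9.72 (chromosome 18 from 63341286 to 63341585) and R428 had 9.63 (chromosome 9 from 83655006 to 83655305). R101 had 9.56 (chromosome 14 from 61969746 to 61970045), R368 had 9.49 and R376 had 9.36 (chromosome 18 from 30044206 to 30044505). With total library size the differences of all regions moved by a log2 of -3.24 in the median, and these 10 lay between 6.11 and 7.32, with R321 at 7.32.

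Higher activity in cortex was called for 100 regions, 34 B, 24 H, 39 L and 3 R regions, and 61 of the 100 had no RNA count in retina. This make-up depends on the fit: construct means in limma gave 57 B, 11 H, 10 L and 5 R regions, and the fits without cortex replicate 1, 2 or 3 gave 8 of 8, 8 of 9 and 7 of 7 as B regions. The 10 with the largest fitted differences were among these 61, so a fold is a bound against a floor of 3 counts over the 3 retina RNA libraries. Activity in retina was at least 342-fold lower for B570 (chromosome 2 from 57759406 to 57759705), at least 381-fold for H437 (chromosome 9 from 104032506 to 104032805) and at least 374-fold for B683, whose constructs spanned 93016064 to 93016679 on chromosome 11. It was at least 311-fold lower for L589 (chromosome 1 from 82231246 to 82231545), 278-fold for L518 (chromosome 19 from 23560726 to 23561025) and 344-fold for L508 (chromosome 3 from 14687286 to 14687585). It was at least 204-fold lower for L700 (chromosome 11 from 79374106 to 79374405), 177-fold for L861 (chromosome 6 from 27982066 to 27982365), 205-fold for B542 (chromosome 18 from 13557746 to 13558045) and 191-fold for H376 (chromosome 10 from 9322666 to 9322965). These bounds cover counting error only, and nonzero H and L counts in retina had medians of 31 to 43 per replicate, so 1 missed molecule can weigh more than the floor. The bounds hold only for the constructs that pass the DNA minimum in this fit. With no minimum count L589 was at a log2 of -5.08 (edgeR adjusted p = 0.189) and L518 at -7.82 (adjusted p = 0.126), and without retina replicate 2 L589 was at -5.44 (adjusted p = 0.192), smaller than their bounds and not called. None of the 10 was called with any cortex replicate left out, and construct means in limma called 2, at -2.48 to -0.51 for all 10. The limma values are centred on the median region, and most retina constructs had no RNA. Lack of RNA in retina alone therefore gives no large negative difference in limma. The group of 100 is fragile. Leaving out any cortex replicate left 7 to 9 regions, and scaling by total library size gave 87 higher and 977 lower in place of 167 and 100. In the main fit 5.0% of regions were called higher in cortex, and 2.06% of unchanged simulated regions. The simulated regions of a tissue shared 1 RNA/DNA ratio, unlike the real classes, so the 2 rates are not directly comparable.

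Fragments that tile one region were then compared with one another. Shares of variance were taken on construct log2 RNA/DNA averaged over the 3 replicates. In retina, 0.596 of the variance among R constructs lay between regions, while 100 reassignments of constructs to regions gave -0.010 to 0.012. Shares computed on single replicates, not printed here, had an SD of 0.015 (n = 3). For B, H and L constructs in retina the share was 0.013, 0.007 and 0.005. In cortex the share was 0.247 for B (SD of the single-replicate shares 0.012) and 0.022, 0.015 and 0.007 for R, H and L constructs. Among R constructs in retina, the correlation between fragments of one region was 0.755 for pairs with a reciprocal overlap of at least 0.8, 0.599 for 0.5 to 0.8, 0.250 below 0.5 and -0.104 without overlap. Among B constructs in cortex it was 0.318, 0.262, 0.150 and -0.002 in the same order. These correlations run across pairs of constructs, which are not independent replicates.

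Within R321, the most active construct in retina was a fragment of 484 bp on the minus strand from 3925760 to 3926243, with a log2 RNA/DNA of 8.32 ± 0.51 (SD, n = 3). The least active spanned 3925592 to 3925990 on the plus strand and still had 5.09 ± 0.83. In R154 the range was from 5.31 ± 1.60, for 42645801 to 42646187 on the plus strand, to 7.16 ± 0.35, for 42645643 to 42646169 on the minus strand. All 6 constructs of R154 and all 11 of R321 were called higher. The constructs of B880 and B662 in cortex spread more widely. In B880, the fragment from 73621332 to 73621736 had 6.87 ± 0.44, while the fragment from 73620856 to 73621399, which covered 94 bp of the window, had -4.09 ± 3.76 with RNA in 1 replicate only and was not called lower (edgeR adjusted p = 0.511). In B662 the values were 6.59 ± 0.78 for 91444638 to 91445169 and -3.96 ± 2.40 for 91444509 to 91444872. This last fragment covered 277 bp of the window, more than the 102 to 169 bp of the 6 called ones, but had 10 RNA counts in all and was not called lower (edgeR adjusted p = 0.394). Of the constructs, 15 of 22 in B880 and 6 of 7 in B662 were called higher. These construct values are scaled over constructs in place of regions, and so have another zero than the region values.

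**Figure D3:**
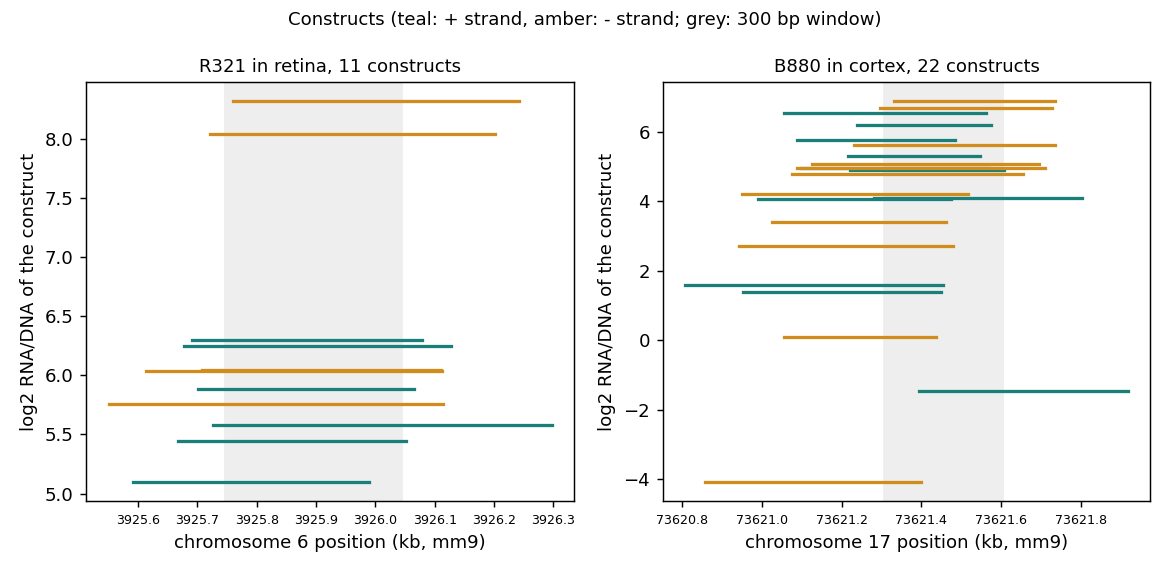
Position (kb, mm9) and log2 RNA/DNA (mean of 3 replicates) of each construct of R321 in retina and of B880 in cortex, with the 300 bp window in grey and the strand by colour. The 11 constructs of R321 lie between 5.09 and 8.32, while the 22 of B880 spread from -4.09 to 6.87.

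Constructs that contained the whole 300 bp window were compared with constructs of the same region that covered less than 150 bp of it, a comparison chosen after the data were examined. In R regions in retina, spanning constructs were higher by a log2 of 2.37 (SE 0.325 over 133 regions, permutation test, adjusted p = 8e-05). RNA in at least 2 replicates was found for 39.0% of spanning and 6.79% of partial constructs. In B regions in cortex the difference was 0.645 (SE 0.152 over 151 regions, permutation test, adjusted p = 0.00024). B, H and L regions in retina gave 0.128, -0.015 and 0.035, and R, H and L regions in cortex gave 0.028, 0.006 and -0.045; none of these passed the permutation test, with adjusted p from 0.277 to 0.956.

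**Figure D4:**
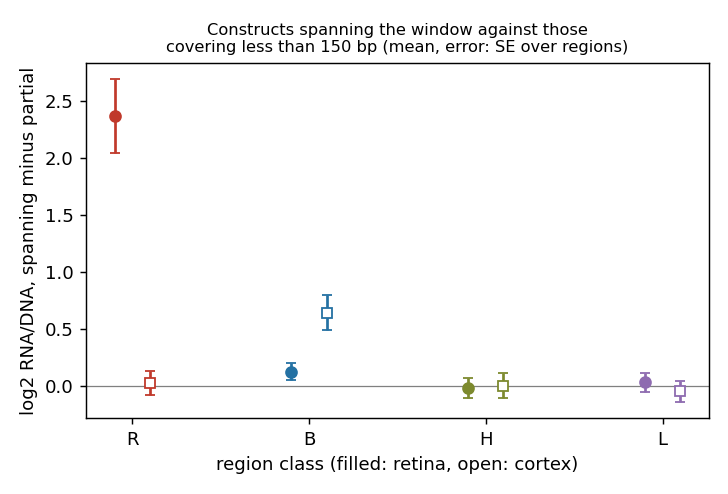
Difference in log2 RNA/DNA between constructs that span the 300 bp window and constructs of the same region that cover less than 150 bp, by class, in retina (filled) and cortex (open); points are means and error bars SE over regions. R regions in retina (2.37) and B regions in cortex (0.645) stand above 0.

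Single constructs followed the same classes. Among constructs called higher by edgeR, 837 of 838 in retina were R constructs and 232 of 258 in cortex were B constructs. These numbers moved with the settings: in retina 452 to 555 were called higher with any replicate left out, 176 with RLE size factors and 530 in DESeq2. In cortex 173 to 315 were called with any replicate left out, 485 without the block and 1085 in DESeq2. The test also called 23374 constructs lower in retina, but 13 to 14 when any retina replicate was left out. Construct log2 RNA/DNA was nearly uncorrelated with fragment length, with a Spearman correlation of 0.012 in retina and -0.036 in cortex. In retina 64.3% of constructs had no RNA count in any replicate, and their values follow the DNA counts and the prior count. The length and strand comparisons in retina therefore cannot show whether activity depends on either. Median log2 RNA/DNA of plus-strand fragments differed from that of minus-strand fragments by 0.039 in retina (permutation test, p = 0.0463) and by -0.047 in cortex (permutation test, p = 0.0779). The retina difference did not pass with at least 50 DNA counts (permutation test, p = 0.368). These strand tests take constructs as independent, although constructs of one region overlap. Between replicates, construct log2 RNA/DNA correlated with a mean Pearson r of 0.548 ± 0.021 in retina and 0.146 ± 0.027 in cortex (SD over 3 pairs, across constructs). Across regions, r was 0.387 to 0.422 in retina and 0.256 to 0.331 in cortex, so the tissues differed less there.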

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

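The tests of sequencing depth and of few RNA molecules below were chosen after the detection rates had been seen, and the splits of the libraries had been counted before their expectation was written down. Differences between retina and cortex are listed because the interaction itself was tested. By region, 167 were called higher in retina and 100 higher in cortex (edgeR). By class, the median difference against the other classes was 3.66 for R, -0.861 for B, -0.867 for H and -0.972 for L, the last 3 against others that include R. The single regions higher in retina were R321 (log2 10.57), R167 (10.27), R154 (10.26), R539 (10.13), R366 (9.86), R335 (9.72), R428 (9.63), R101 (9.56), R368 (9.49) and R376 (9.36). Those higher in cortex had fitted log2 differences of -14.63 (B570), -14.42 (H437), -14.39 (B683), -14.27 (L589), -14.08 (L518), -13.91 (L508), -13.78 (L700), -13.77 (L861), -13.60 (B542) and -13.53 (H376). These fitted values arise from zero RNA counts in retina and are no bounds; the folds against a floor of 3 counts were at least 177 to 381.

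Chance was examined by splitting the libraries in other ways. Each of the 6 tests of constructs or regions has 10 splits, too few for a share under 0.05. In each of the 6, 1 split, the real one, gave as many calls, and the highest of the other splits gave 0, where the real region tests called 182 in retina, 63 in cortex and 267 for the difference, and the construct tests 24212, 261 and 1774. The other splits mix RNA with DNA libraries, or retina with cortex replicates, within a group. The real difference then adds to the spread, so few or no calls were to be had there. The 0 is therefore no chance level, and chance stays open.

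Signal outside the main measurement was found among constructs with too little DNA to be tested. In retina, 167 of 9665 such constructs had more than 3 RNA counts in each of the RNA libraries, 166 of them R constructs, with a median of 1821 RNA counts over the 3 libraries. In cortex, 79 of 6844 did, 43 of them B constructs, with a median of 433 RNA counts.

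The first pattern weighed is that RNA of fewer constructs was seen in retina than in cortex, on which many of the regions higher in cortex rest. Depth is argued against: with each RNA library thinned to 3840752 counts, cortex exceeded retina by 45.8 percentage points of constructs with RNA (63.3% ± 4.62 against 17.5% ± 2.49, SD, n = 3). RNA reads taken up by R constructs are argued against as the whole cause. With H and L constructs of cortex thinned to the H and L total of retina, cortex still exceeded retina by 43.1 points (54.6% ± 4.51 against 11.5% ± 2.53). Thinning removes reads and not molecules, and nonzero H and L counts in cortex had medians of 62 to 108. Whether R transcripts crowded out other RNA molecules before sequencing was therefore not tested and stays open. Few RNA molecules per construct, each read many times, stays open, since 16.4% of nonzero H and L counts in retina were 1 to 3, where shallow reading of many molecules would give mostly such counts. In cortex 9.39% to 12.1% were 1 to 3, so this does not separate the tissues by itself, and tissue, delivery and age stay open as untested.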

How the results depend on the processing

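The analyses without the top construct of each region and with the deposited log2 values of the authors were added after the data were examined; the others were set before. The class comparisons were run with other minimums, construct means in limma and each replicate left out. They were not run with another scaling, DESeq2 or no block. Of 108 alternative values of class shares among regions called higher, all stayed on the same side of the test. So did 103 of 108 class medians. The exceptions were B minus others in retina (-0.251, not passing), which passed at -0.788 with at least 3 constructs and lay between -0.711 and -0.026 with a retina replicate left out, passing without replicate 1 (-0.711, adjusted p = 0.00249) and 2 (-0.564, adjusted p = 0.0323) but not without 3 (-0.026, adjusted p = 0.905); L minus others for retina minus cortex, which did not pass at -0.089 with construct means in limma; and L minus others in cortex, which ranged from -0.136 to -0.075 with a cortex replicate left out and did not pass without replicate 1 (adjusted p = 0.0596). Sizes moved more than sides: construct means in limma gave R minus others 0.937 in retina (3.45) and 1.292 for the difference (3.66). Among alternative values of named regions 572 kept sign and call, 61 kept the sign but not the call, and B352 in cortex reversed to -0.01 without its top construct; B352 has 98.3% of its retina RNA in 1 construct. Total library size moved all regions by a log2 of -3.54 in retina, -0.37 in cortex and -3.24 for the difference (medians).

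Counts of calls, which were also taken with other scalings, DESeq2 and no block, moved more, mostly the lower ones. Scaling by total library size gave 89 higher and 924 lower regions in retina (main 179 and 3), 18 lower in cortex (0), and 87 higher and 977 lower for retina minus cortex (167 and 100); for constructs in cortex it gave 8 lower (3). DESeq2 gave 438, 26 and 576 lower regions; among constructs it gave 530 higher in retina (838), 1085 higher and 18087 lower in cortex (258 and 3), and 881 higher and 20606 lower for the difference (409 and 1365). RLE size factors gave 176 higher constructs in retina, 1 lower in cortex, and 126 higher and 5848 lower for the difference. Without the replicate block, 113, 1 and 172 regions were lower; constructs gave 485 higher and 6420 lower in cortex and 1070 higher and 17421 lower for the difference. The block moved no count of higher regions by over 1.5 times. At least 50 DNA counts gave 21 lower regions in retina and 2 in cortex, and 14814, 1 and 2121 lower constructs in retina, cortex and the difference. No minimum count gave 66 lower constructs in retina. At least 3 constructs gave 174 and at least 10 gave 32 lower regions for the difference; at least 10 gave 2 lower in cortex. Construct means in limma gave 26 lower regions in retina and 7 in cortex, and leaving out the top construct 295 and 2. The causes were not tested, beyond the fewer regions or constructs that a stricter minimum leaves.

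Class shares among lower regions held less well. For the difference, B regions had a larger share than the others (adjusted p = 0.00752), but not with at least 10 constructs (0.0971) or without retina replicate 1 (0.148). The smaller R share (3.69e-08) was lost with any cortex replicate left out (0.21 to 0.695). H (1.0) and L (0.101) passed in some fits, but in opposite directions. In limma both had a smaller share than the others, H with 2.28% (0.0178) and L with 1.62% (0.000105). H had a larger share without retina replicate 1 (12.35%, 0.018), and L without retina replicate 3 (13.11%, 0.00792). All values in brackets are adjusted p of Fisher's exact tests.

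With each replicate left out in turn, lower regions numbered 0 to 2 in retina, 0 to 7 in cortex and 7 to 291 for the difference (7 to 9 without a cortex replicate, 186 to 291 without a retina replicate). Constructs in retina numbered 452 to 555 higher and 13 to 14 lower, constructs in cortex 1 to 4 lower, and the difference 231 to 352 higher and 163 to 885 lower.

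The share of variance between regions for B in cortex (0.247) was 0.217 with a prior count of 0.5, 0.269 with 5 and 0.179 with the deposited values; over all classes in cortex (0.098) it was 0.092 with at least 50 DNA counts, 0.083, 0.110 and 0.065 in that order, and in retina (0.513) 0.555 with at least 50 DNA counts and 0.555 with the deposited values. The length correlation was -0.042 and 0.017 with at least 50 DNA counts, and -0.039 and 0.022 after subtracting region means, in cortex and retina. The strand difference was -0.051 in cortex (permutation p = 0.0342, with constructs taken as independent) and 0.014 in retina after subtracting region means, and 0.018 in retina with at least 50 DNA counts. With that minimum the deposited values correlated with a Spearman rho of 0.978 in cortex and 0.716 in retina (Pearson r 0.97 and 0.939).

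The planned motif, GC and gene list analyses were not run, for lack of a genome and of gene names here. A 4-fold increase of a simulated region was called in 0% of cases in retina and 98% in cortex, where the common dispersion of the fits was 1.5 and 0.185; no test ties this to depth.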

Other observations

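The counts of shared regions, the test of fragment length and the test of nearby targets were chosen after their results had been seen; the tests of DNA coverage, of orientation and of single constructs were set before theirs. Regions outside the R class showed little activity that repeated between single retina replicates. With the 95th percentile of H and L regions as background in each replicate, 22 of 439 B regions lay above it in each retina replicate, but a pair of replicates shared only 1 to 2 of them, where independent lists share 1.1. On the mean of the retina replicates, 39 of 439 B regions lay above the percentile, 8.88% (95% exact binomial interval 6.39 to 11.94). H and L regions gave 5.52% and 4.63% there, so a small excess of B regions in retina is not excluded. R regions above the background numbered 204 to 230 of 477, and pairs of replicates shared 170 to 183, where independent lists share 92.8 to 104.6. In cortex, 73 to 93 of 461 B regions lay above it and pairs shared 55 to 66 (13.5 to 17.2 for independent lists). R regions in cortex numbered 26 to 29 of 494, with 6 to 12 shared (1.42 to 1.59 for independent lists). Pairs of cortex replicates also shared 4 to 5 H regions (1.48 to 1.71) and 2 to 5 L regions (1.26 to 1.44). Some sharing above independent lists in cortex was thus not particular to R regions. H and L regions, which set this background, are not independent of it. B regions in retina exceeded H and L regions in the median by 0.53 (permutation test, adjusted p = 0.0183). The difference was positive in each replicate (1.032, 0.646 and 0.049) but varied widely, with a mean of 0.576 ± 0.496 (SD, n = 3).

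A small set of regions was active outside the class of the tissue. In retina these were B141 (log2 1.81, SE 0.49, chromosome 1 from 133207026 to 133207325) and B352 (3.52, SE 0.58), of which B352 had 98.3% of its RNA counts in 1 construct. Without that construct B352 fell to -1.3 in retina (SE 3.22, edgeR adjusted p = 0.786). In cortex they were H929 (0.73, SE 0.18, chromosome 7 from 122610326 to 122610625) and 7 R regions. R885 (4.14) and R523 (4.06) were the highest of these, followed by R247 (2.06, chromosome 12 from 36199386 to 36199685) and R72 (2.00, chromosome 4 from 117486446 to 117486745). R462 (1.54, chromosome 3 from 19900786 to 19901085), R712 (1.49, chromosome 15 from 72484086 to 72484385) and R13 (1.19, chromosome 6 from 115888886 to 115889185) were lower. The cortex set moved with the settings. R regions called there numbered 3 with construct means in limma, 4 without cortex replicate 3 and 10 without cortex replicate 1. With at least 50 DNA counts, or without cortex replicate 3, 0 H regions were called, so the call of H929 was lost. In retina, R72 (7.73), R247 (5.14) and R523 (3.82) were called higher too, while R885, R13, R462 and R712 were not (adjusted p from 0.438 to 0.953). R885 was higher in cortex than in retina (log2 difference -9.84, SE 2.34, edgeR adjusted p = 0.0201), but did not pass without the block (adjusted p = 0.0662), without retina replicate 1 or 3 (0.0924 and 0.0934) or without cortex replicate 1 or 3 (0.0929 and 0.0818). R72 was higher in retina (5.79, SE 0.29, adjusted p = 1.21e-07), and R523 did not pass that test (-0.19, SE 0.54, adjusted p = 0.842).

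For the R regions active in cortex, sequence of a nearby B target inside the fragments is argued against: the closest fragment of any B target lay 14480 bp away, and fragments had at most 702 bp. Such neighbours were rare by design, with 1 of 858 R targets having a B fragment within 1000 bp, and sites that were not targeted are not covered. A single construct with outlying counts cannot be told apart for all of them: when each region lost the construct with most RNA counts, 4 of the 7 (R13, R523, R72 and R885) were still called, fewer than the 5 set beforehand to exclude it, and R247, R462 and R712 were not. Their log2 values went from 1.54 (SE 0.35) to 1.32 (SE 0.49, edgeR adjusted p = 0.25) for R462, from 1.49 (SE 0.29) to 1.06 (SE 0.38, adjusted p = 0.219) for R712 and from 2.06 (SE 0.37) to 1.22 (SE 0.57, adjusted p = 0.445) for R247. All 3 stayed above 0 while the SE grew, so the lost calls do not by themselves point to an outlying construct, although R247 fell by more than the others. Open chromatin of these sites in brain is a biological candidate that was not tested.

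Constructs spanning the whole window exceeded partial ones in R regions in retina and B regions in cortex. Fragment length is argued against as the cause. Among fragments above and at or below the median length, the smaller difference was 2.71 for R regions in retina (SE 0.477) and 0.67 for B regions in cortex (SE 0.296), the latter with an adjusted permutation p of 0.0974. DNA coverage is argued against too, since with at least 50 DNA counts the difference was 2.84 (SE 0.41, 93 regions) for R in retina and 0.53 (SE 0.22, 90 regions) for B in cortex. A hypothesis that remains is that sequence inside the window, or spread over most of it, may be needed for activity. In B662 the lowest fragment covers 277 bp of the window and the most active 148 bp, but the former is 1 construct that was not called lower (edgeR adjusted p = 0.394), so inactivity is not separated from missed RNA. Motifs were not analysed here.

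A further hypothesis was that activity depends on the orientation of the fragment. Pairs with a reciprocal overlap of at least 0.8 correlated with r = 0.771 in the same and 0.739 in opposite orientation among R constructs in retina, a difference of 0.032 (95% bootstrap interval over regions 0.017 to 0.049). Among B constructs in cortex r was 0.343 and 0.292, a difference of 0.051 (0.018 to 0.086). Both intervals lie above 0 and below the 0.1 set beforehand, so a small effect of orientation may exist while a large one is argued against.

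Read counts of the barcodes in the plasmid table correlated with DNA counts in the tissues by a Spearman rho of 0.332 to 0.371 in retina and 0.387 to 0.427 in cortex, across 45670 constructs.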
